A study of Mus musculus with 3 samples.

How the data were processed

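RNA from 3 pooled cell sorts of female BALB/c mice aged 6 to 8 weeks was sequenced, giving 1 library per group. MDSCs (myeloid-derived suppressor cells, immature myeloid cells that restrain T cells) came from 20 tumours of mice given alisertib, an inhibitor of the Aurora A kinase, and from 20 tumours of control mice. Neutrophils came from the bone marrow of 5 wild-type mice. The labels call the control mice both untreated and control treated, so whether they received a vehicle is unknown. Per the labels' protocols, cells were isolated on a FACSAria sorter to a purity above 90%, total RNA was extracted with Trizol, and libraries were made with the NEBNext Ultra kit. The labels name neither the surface markers of the sort nor the tumour line, dose, schedule or RNA selection.

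The authors deposited a table of raw read counts per gene and a table of FPKM values (fragments per kilobase of gene, scaled to library depth). CASAVA 1.8, STAR 2.5.1b and the mouse genome builds mm9 and mm10 are named per the submitters' processing notes, without a role or order. The counting tool, the annotation, the strand setting and the filter on genes are not given in the sources used here. Strand is therefore not assumed, and genes that overlap or share reads with close copies are uncertain. The count table held 19723 genes and that of FPKM values 23327, of which 19173 were in both. The 550 genes found in the count table alone had 0 counts in every library. The 4154 genes found in the FPKM table alone were left out of the comparisons. Dividing counts by the deposited FPKM values and the gene length (the union of a gene's exons) implied FPKM library sizes of 21374376, 20054125 and 23323763 for the alisertib, control and bone marrow libraries, which differ from the count totals. Of 8185 genes with a known length and over 50 counts in every library, 73.1% lay within 0.5% of the implied size. Gene symbols came from GENCODE M21 for 19648 of the 19723 genes, and 75 had no symbol. Positions are from the same annotation, on GRCm38, and were not given by the deposited tables.

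All comparisons used the raw counts, which summed to 19373087, 21959748 and 21987097 in the alisertib, control and bone marrow libraries. Library sizes were scaled by TMM factors (edgeR 4.0.16, R 4.3.3) of 1.07148, 0.88952 and 1.0492. Genes with at least 1 CPM (counts divided by the scaled library size in units of 1e6) in at least 1 library were kept, which left 13019 genes, of which 86.3% were protein coding. The log2 ratio was taken after adding 0.5 to each count. Its 95% interval was the exact (Clopper-Pearson) interval of the ratio given the summed count. A gene was called higher or lower when the bound nearest to 1 was at least 2-fold. Where a library held 0 counts, a fold was computed against a floor of 3 counts in that library and is given as "at least". That floor was 0.145, 0.154 and 0.130 CPM in the 3 libraries. With 1 to 3 counts the ratio is given with its interval. Intervals and floors cover counting error only, as there was 1 library per group. Reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error.

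With 1 library per group there are no replicates. No p-value or spread between animals was computed, and each comparison describes these libraries. The 43 gene lists cover neutrophil identity and granules, myeloid function, cytokine and chemokine signalling, antigen presentation, cell cycle, cell death, stress, metabolism, transcripts of the ribosome, mitochondria and histones, and markers of other cell types. The lists, the size rule, the rule for named genes and the alternatives below were chosen before the data were examined, except where stated. For each list, the median log2 ratio of the members past the filter was ranked among 10000 random lists of the same size, matched on mean log2 CPM in 20 bins. A list was taken as outside the random lists below percentile 2.5 or above 97.5. If lists were independent, chance would place 2.2 of 43 there. Random lists do not keep the correlation between genes of a list, so the percentile is a description.

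The genes named were Aurka and Aurkb; the 10 higher and 10 lower genes per comparison with the largest bound nearest to 1, at 10 CPM or more in the higher library, passing over unnamed gene models, LOC, Mir and Snor symbols; up to 4 members of each list, called genes before others and then the most abundant; and Arg1, Nos2, S100a8, S100a9, Cybb, Ncf1, Stat3, Jak2, Cd274, Ptgs2, Il1b, Ly6g, Itgam and Csf3r. Some genes that met this rule are not reported here.

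The procedure was tested on simulated counts drawn from the real gene means of the control library, at the sizes of the alisertib and control libraries, with 200 of 13019 genes changed. Of the 50 genes changed at each size, 72.0% were called at 3-fold, 86.0% at 4-fold, 96.0% at 8-fold and 94.0% at 16-fold, and 2 of 12819 unchanged genes were called. When each library was given an assumed biological coefficient of variation of 0.2, 51 unchanged genes were called. At 0.4 the number was 1425, more than all genes called between the alisertib and control libraries. A planted list of 20 doubled genes reached percentile 100, and 15 of 200 unchanged lists (7.5%) lay outside the random bounds.

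The alternatives tried were DESeq2 1.42.0 size factors, total counts, total counts without the 20 most abundant genes of each library, no filter, a filter at 10 CPM, bounds of 1.5-fold and 4-fold, a log2 ratio of at least 1 whatever its interval, the authors' FPKM with pseudocounts of 1 and 0.1, libraries thinned to the shallowest depth, means in place of medians, and random lists not matched on abundance. After the data were seen, 2 more were added: the genes of the FPKM table alone, with counts rebuilt from their FPKM, and the counts of called genes without the members of the T, NK, B and plasma cell lists. Total counts moved the median log2 ratio of all genes by 0.27 in alisertib over control and by -0.24 in control over bone marrow. Leaving out the most abundant genes moved it by 0.24 and -0.27. These scalings moved the alisertib over bone marrow median by under 0.1. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.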

Results

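Gene expression was measured by RNA sequencing in MDSCs (myeloid-derived suppressor cells) sorted from tumours of alisertib-treated mice, in MDSCs sorted from tumours of control mice, and in neutrophils sorted from the bone marrow of wild-type mice. Each group was 1 library, pooled from 20 tumours, 20 tumours and 5 mice, so there were no replicates and every difference below is between these libraries. The alisertib library held 19373087 counts, the control library 21959748 and the bone marrow library 21987097, with 17622, 17303 and 17349 genes detected. The most abundant gene was the ferritin heavy chain gene Fth1 in both tumour libraries (2.75% of counts with alisertib and 3.13% in control) and the calprotectin subunit gene S100a9 in bone marrow (3.19%).

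Across the 13019 genes past the filter, log2 expression correlated closely between the alisertib and control libraries (Spearman correlation across genes 0.975) and less between either of them and bone marrow (0.803 and 0.81). Between alisertib and control, 234 genes were higher and 154 lower with alisertib, 2.98% of all, and 69.8% of genes lay within 1.5-fold. Control MDSCs differed from bone marrow neutrophils at 2386 higher and 2985 lower genes, and alisertib MDSCs at 2436 and 2908.

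The comparison of alisertib with control MDSCs asked how the drug's target and the genes of tumour MDSCs differed after treatment. Aurka, which encodes the mitotic kinase that alisertib inhibits (ENSMUSG00000027496, chromosome 2, 172356190 to 172370535 on the minus strand of GRCm38), had 213 counts with alisertib and 189 in control, 10.3 and 9.68 CPM. Its ratio of 1.06 had an interval of 0.868 to 1.30, so no difference was detectable at this depth. Aurkb, the related kinase of the chromosomal passenger complex, had 6 counts in each.

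Neutrophil granule genes were lower with alisertib. Of 18 secondary and tertiary granule genes, 11 were called lower and none higher, 17 had a ratio below 1, and their median log2 ratio was -1.5 (percentile 0.0 among random lists). Ngp, encoding neutrophilic granule protein (ENSMUSG00000032484, chromosome 9, 110419747 to 110423012), was 8.13-fold lower (7.86 to 8.41), at 3855 against 29483 counts. The iron-binding protein lactoferrin (Ltf, ENSMUSG00000032496, chromosome 9, 111019271 to 111042767) was 4.54-fold lower (4.36 to 4.75) and the antimicrobial cathelicidin gene Camp (ENSMUSG00000038357, chromosome 9, 109847379 to 109849617) 4.66-fold lower (4.05 to 5.38). Cd177, a neutrophil surface glycoprotein, was 3.57-fold lower. The 20 neutrophil identity genes, 8 of which are also in another list, had a median of -0.57 (percentile 0.05), with 4 called lower: Retnlg (4.96-fold), the peptidoglycan-binding gene Pglyrp1 (3.56-fold) and the calprotectin genes S100a8 (2.61-fold, 2.59 to 2.63) and S100a9 (2.41-fold, 2.39 to 2.42). S100a8 (ENSMUSG00000056054) and S100a9 (ENSMUSG00000056071) lie on chromosome 3, at 90668978 to 90670035 and 90692632 to 90695721. Primary granule genes were few and low in tumour MDSCs: the median of 10 was -0.45, or -0.17 with the gene at 0 counts set to its bound, and only the protease inhibitor gene Serpinb1a was called, 3.26-fold lower.

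Outside these lists, the genes with the most firmly lower counts were Ifitm6 (7.95-fold, 7.42 to 8.55), the histone-citrullinating enzyme gene Padi4 (5.51-fold, 4.86 to 6.28), the transglutaminase gene Tgm1 (5.29-fold) and the glutathione-cleaving enzyme gene Ggt1 (4.41-fold). Actb (3.86-fold) and the stefin gene Stfa3 (4.0-fold) were lower too, but both have close copies that can share reads. Ly6g, a surface marker of mouse neutrophils, was 1.37-fold lower, the integrin gene Itgam 1.46-fold and the granulocyte colony-stimulating factor receptor gene Csf3r 1.29-fold, none of them past the 2-fold bound.

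Lymphocyte genes were higher with alisertib. Of 21 T and NK cell markers, 12 were called higher and none lower, with a median log2 ratio of 1.87 (percentile 100). The T cell transcription factor gene Tcf7 was 8.43-fold higher (5.57 to 13.9), at 210 against 23 counts, the T cell receptor constant gene Trbc1 8.29-fold and Cd2 6.21-fold. Of 19 B and plasma cell markers, 11 were called higher and none lower, with a median of 3.02, or 2.75 with genes at 0 counts set to their bound (percentile 100). The B cell receptor component Cd79a was 8.53-fold higher, the kinase gene Blk 14.1-fold (5.88 to 59.5) and the IgM heavy chain Ighm 6.92-fold (5.30 to 9.31). Levels were low, with medians of 4.82 CPM for the T and NK list and 2.94 CPM for the B list, against 1.18 and 0.36 CPM in control. The 10 higher genes with the firmest bounds held further genes of lymphocytes, such as the transcription factor gene Lef1 (30.2-fold, 14.7 to 89.9) and the GTPase genes Gimap3 (15.5-fold) and Gimap6 (9.15-fold), which have close copies. Lrig1, a regulator of growth factor receptors (ENSMUSG00000030029, chromosome 6, 94604529 to 94700158), was 95-fold higher (32.5 to 984), at 252 against 2 counts. Ablim1 was 18.5-fold higher, Gramd3 12.1-fold and Pou6f1 10.1-fold.

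Genes of hypoxia and glycolysis were lower, with a median log2 ratio of -0.61 over 34 genes (percentile 0.0), of which 31 lay below 0 and 5 were called lower. These included the oxidoreductase gene Ero1l (2.36-fold), the glycolytic enzyme gene Pfkl (2.22-fold), the oxygen sensor gene Egln3 (2.15-fold) and the glucose transporter gene Slc2a1 (2.07-fold). None of these named genes was still called with total counts. Cholesterol synthesis and efflux genes had a median of -0.28 (percentile 0.97), with Stard4, a sterol carrier, 2.54-fold lower. Total counts raised the log2 ratios of this comparison by 0.27, nearly the size of that median, and Stard4 was then no longer called. JAK-STAT3 components and targets had a median of -0.43 (percentile 0.97) with 1 gene called in each direction, but their mean lay inside the random lists (percentile 12.1).

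Interferon-stimulated genes were higher, with a median of 0.34 over 36 genes (percentile 100) and 4 called, all of the interferon-induced tetratricopeptide family: Ifit2 (3.59-fold, 3.09 to 4.21), Ifit1 (2.87-fold), and Ifit3 (3.95-fold) and Ifit3b (3.29-fold), which are near-identical and not separable with certainty. MHC class II and costimulation genes had a median of 0.60 over 13 genes (percentile 99.97). H2-Ob, a B cell modulator of antigen loading, was 5.50-fold higher (2.82 to 13.2) and Cd74, the invariant chain, 1.69-fold, in the library in which B cell markers were also higher. Ribosomal protein genes were slightly higher as a group, with a median of 0.28 over 86 genes (74 above 0, percentile 100) and none called. That list was chosen as a gauge of RNA quality, so a technical difference between the tumour libraries cannot be told apart. Chemokine genes had a median of 0.28 (percentile 99.38), with the monocyte attractant Ccl8 called 8.03-fold higher (4.08 to 20.4) and Ccl22 5.09-fold lower (2.56 to 12.4). Antioxidant and NRF2 target genes (median 0.19, percentile 100), MHC class I genes (0.22, 99.93), heat shock genes (0.24, 99.64), G2/M and mitosis genes (0.52, 98.11) and monocyte and macrophage markers (0.32, 97.88) also lay above random lists. None of these 5 groups had a gene called higher, and the chaperone gene Hspa1a, which has the close copy Hspa1b, was 2.12-fold lower. All these groups were higher in the same library as the lymphocyte markers.

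Suppressive function genes of myeloid cells lay just inside the random lists, with a median of -0.42 over 20 genes (percentile 3.05), but below them with FPKM plus 1 (2.20), with means (0.93) and against lists not matched on abundance (0.10). Inducible nitric oxide synthase, Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), was 2.31-fold lower (2.19 to 2.43), at 2094 against 4545 counts, and Wfdc17 2.94-fold lower. The arginase gene Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484) was 1.5-fold lower (1.41 to 1.59) and the checkpoint ligand PD-L1, Cd274 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095), 1.16-fold higher (1.14 to 1.18), neither past the bound. NADPH oxidase subunit genes had a median of -0.47 over 9 genes (percentile 6.93), with Cybb 1.42-fold and Ncf1 1.94-fold lower. The kinase gene Jak2 was 1.63-fold lower and Il1b 1.45-fold, while Stat3 (log2 ratio -0.15) and Ptgs2 (-0.25) lay at 0.12 and 0.02 with total counts. The trend of the ratio with abundance given above applies to modest decreases here too.

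Further lists lay inside the random lists in the main analysis, and the medians of several turned positive with total counts. These were NF-kappaB genes (-0.16, or 0.11 with total counts), cytokines (-0.22, or 0.05), pattern recognition receptors (-0.19, or 0.08), immune checkpoint genes (-0.17, or 0.10), pro-apoptotic (-0.14, or 0.13) and anti-apoptotic genes (-0.02, or 0.25), p53 targets (-0.04, or 0.23), unfolded protein response genes (-0.07, or 0.20), nuclear oxidative phosphorylation genes (-0.16, or 0.10), lysosomal genes (-0.08, or 0.19), myeloid transcription factors (-0.22, or 0.05) and histone genes (-0.05, or 0.22). Chemokine receptors (-0.35, percentile 3.05) and immediate early genes (-0.33) stayed below 0 under each scaling, and G1/S genes (0.23) and progenitor genes (0.24) above it. Lipid genes (0.03) and mitochondrially encoded genes (0.03) lay at -0.03 with DESeq2 size factors. Single genes called in these lists included Bcl2 (4.24-fold higher), Myc (3.08-fold higher), the fatty acid desaturase gene Scd1 (7.11-fold higher), osteopontin (Spp1, 2.14-fold higher), the early response gene Egr1 (3.37-fold lower), the stress transcription factor gene Xbp1 (2.40-fold lower), Osm (2.09-fold lower) and the histone gene Hist1h1c (2.09-fold lower). Bcl2 stood at 7.03 and 1.64 CPM, in the low range of the lymphocyte markers that were higher in the same library. Which cells of the pools carried these differences is not known.

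Markers of non-lymphoid cells other than macrophages and neutrophils lay inside random lists in the main analysis, but those of eosinophils, mast cells and basophils lay below them with the 10 CPM filter (1.27) and fibroblast genes with means (0.87). Dendritic cell markers had a median of 0.10, with the migration receptor gene Ccr7 6.43-fold higher (4.77 to 9.01), a gene that lymphocytes express as well. Medians were -0.09 for eosinophil, mast cell and basophil markers (0.18 with total counts), -0.05 for erythroid and platelet markers (0.22), and -0.11 for fibroblast and matrix genes (0.16), in which the collagen gene Col5a1 was 5.96-fold lower (3.57 to 11.1). Epithelial and mammary tumour markers had a median of 0.08, or 0.00 with the gene at 0 counts set to its bound and -0.13 with the 10 CPM filter. Endothelial markers had 0.35, or 0.30 at the bound, with Vwf 2.68-fold higher.

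Of the 43 lists, 16 lay outside random lists in this comparison, 11 above and 5 below. The share of called genes that were higher was 60.3%, but 83.6% with total counts, 81.3% without the most abundant genes and 34.6% with the 10 CPM filter, and with total counts Nos2, S100a9, Ero1l, Pfkl, Egln3, Slc2a1, Stard4, Xbp1, Osm, Hspa1a and Hist1h1c were no longer called. Some lists outside the bounds moved inside under another setting: antioxidant (91.8), chemokine (96.4), MHC class I (90.5) and heat shock genes (92.1) against random lists not matched on abundance, and G2/M (90.0) and macrophage genes (88.0) when means replaced medians. Others moved outside. Besides suppressive function genes, these were, below the random lists, primary granule genes (1.54 with FPKM plus 0.1 and 0.83 without matching), chemokine receptors (1.52 with FPKM plus 1 and 0.63 without matching), immediate early genes (0.33) and NADPH oxidase genes (1.13) without matching, and nuclear oxidative phosphorylation genes with FPKM (1.81 and 2.08). The latter list stood at percentile 2.64 in the main analysis and 2.28 under each other scaling. Scaling moves all genes alike, so that change came only from a new draw of random lists. Above them were lysosomal genes with means (99.58) and mitochondrially encoded genes with the 10 CPM filter (98.34).

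**Figure D1:**
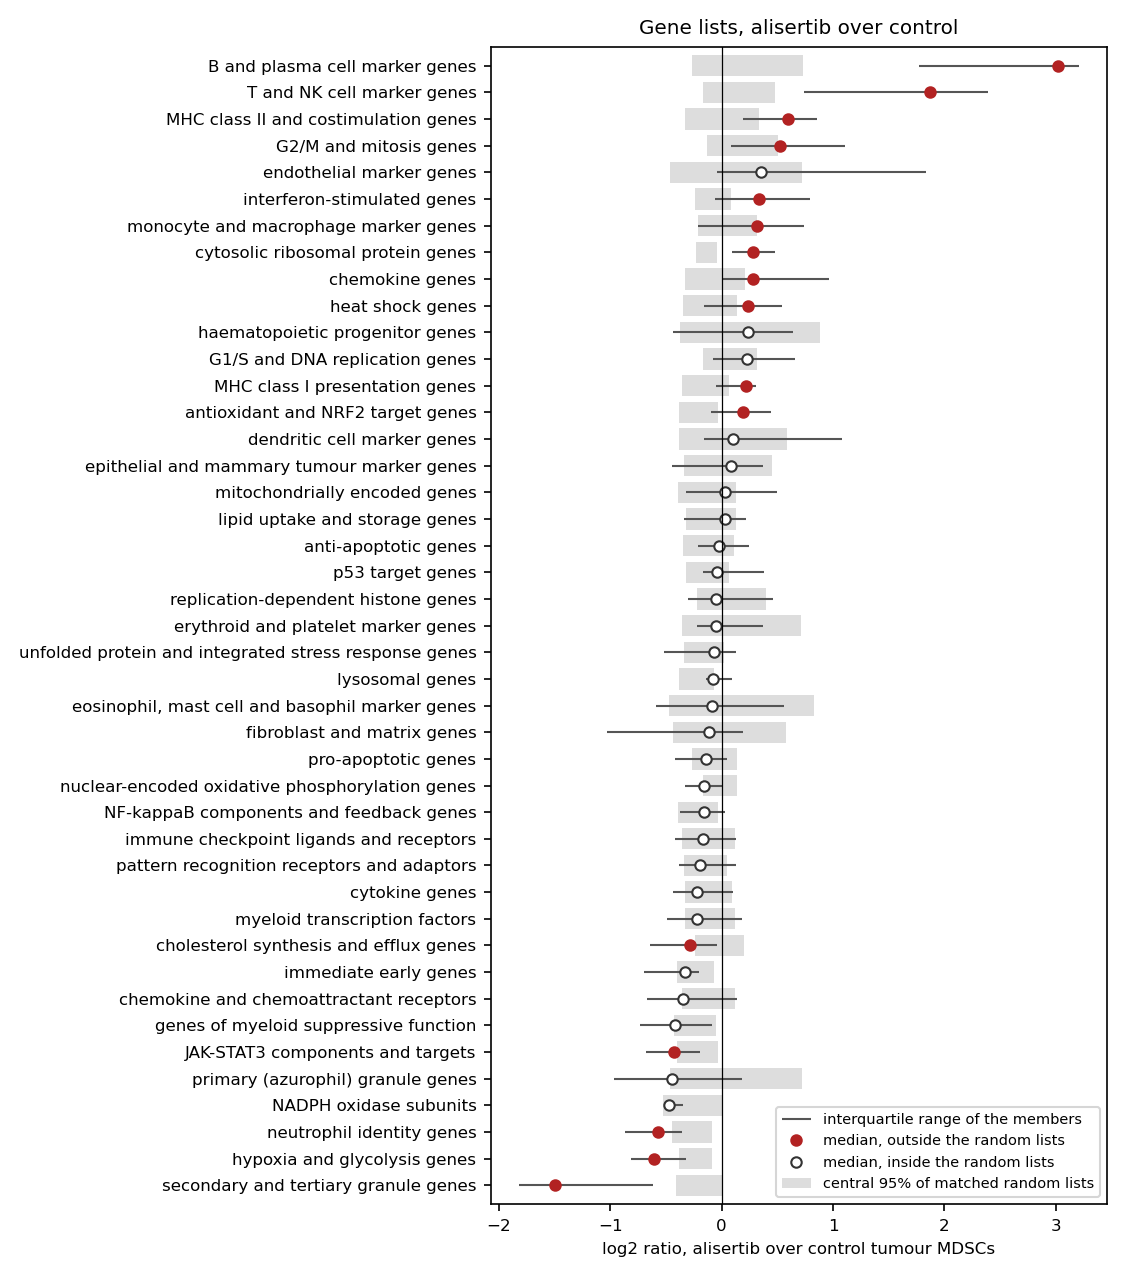
Median log2 ratio of alisertib over control MDSCs (horizontal axis) for 43 gene lists (vertical axis), with the interquartile range of the members as a line, the central 95% of matched random lists as a grey bar, and filled points for medians outside it. B and plasma cell markers (3.02) and T and NK cell markers (1.87) lay farthest above the random lists and secondary and tertiary granule genes (-1.5) farthest below, while several open points below 0 moved above 0 with total counts.

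The comparison of control MDSCs with bone marrow neutrophils asked how tumour MDSCs differ from neutrophils of healthy mice. Inflammatory and suppressive genes were far higher in control MDSCs. Saa3, an acute phase protein (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), was 3288-fold higher (1444 to 13579), at 12529 against 4 counts. Nos2 had 4545 counts against 3, a ratio of 1534 (612 to 8679). Arg1 was 291-fold higher (166 to 637), at 2584 against 10 counts, and Cd274 111-fold (97.7 to 127), at 1099.9 against 9.88 CPM. Of 20 suppressive function genes, 14 were called higher and none lower, with a median log2 ratio of 2.63 (percentile 100).

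Chemokine genes had a median of 4.2 over 18 genes, or 3.70 with genes at 0 counts set to their bound, with 15 called higher. The neutrophil attractants Cxcl3 (565-fold, 466 to 699) and Cxcl2 (39.8-fold, 38.9 to 40.8) were among them, with Cxcl1 (41.9-fold) and Ccl2 (44.7-fold). Cytokine genes had a median of 2.52 with 17 higher and 4 lower, among them Il1a (315-fold, 224 to 475), Lif (120-fold) and Areg, at least 114-fold higher over 0 counts in bone marrow. Il10 had 403 counts against 1, a ratio of 318 (84.9 to 18845). Il1b was 4.99-fold higher and Ptgs2, which makes prostaglandins, 3.22-fold. NF-kappaB genes (median 1.8, 17 higher, none lower) included the feedback inhibitor Tnfaip3 (10.4-fold) and the adhesion gene Icam1 (42.0-fold). Interferon-stimulated genes (median 1.45, 20 higher, 2 lower) included Isg15 (14.7-fold), Gbp5 (32.0-fold) and Oas1a, with 798 counts against 1 (ratio 629, 169 to 37270). Oas1a has close copies, so its share of reads is uncertain. JAK-STAT3 genes (1.23, 12 higher) included Socs3 (13.2-fold) and Cish (32.7-fold), with Jak2 6.69-fold higher and Stat3 1.83-fold, the latter short of the bound. Pattern recognition genes (1.30, 14 higher) were led by the lipopolysaccharide co-receptor Cd14 (32.3-fold), while the flagellin receptor Tlr5 was 14.0-fold lower. Among checkpoint genes (0.57, inside the random lists), Havcr2 was 159-fold higher (92.6 to 334) and Pirb 7.93-fold lower.

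Hypoxia and glycolysis genes had a median of 2.44 over 34 genes with 25 higher and 3 lower, including P4ha1 (38.2-fold), Mif (53.4-fold) and Egln3 (19.3-fold). Antioxidant genes (0.94, 11 higher, 4 lower) included heme oxygenase, Hmox1 (99.3-fold, 94.9 to 104), the cystine transporter Slc7a11 (28.2-fold) and Srxn1 (110-fold). Unfolded protein and integrated stress response genes (1.27, 14 higher, none lower) included Ppp1r15a (23.3-fold). Medians above random lists were also found for p53 targets (1.5; Cdkn1a 55.5-fold), immediate early genes (1.20; Maff 46.7-fold), lysosomal genes (1.42; Cd68 14.2-fold), lipid genes (0.80; Hilpda 319-fold), pro-apoptotic (0.68; Bnip3 18.5-fold) and anti-apoptotic genes (0.89; Traf1 96.7-fold), myeloid transcription factors (0.93; Bhlhe40 10.1-fold), MHC class II genes (1.76; H2-Eb1 5.50-fold), histone genes (1.87; Hist1h1e 6.81-fold) and ribosomal protein genes (0.40; Rps27 2.72-fold). The histone and ribosomal protein lists were chosen as gauges of RNA quality. The labels do not name the RNA selection, so a technical difference between these libraries cannot be told apart. Heat shock (0.58), cholesterol (0.30) and MHC class I genes (0.68) lay inside the random lists, although the sterol exporter gene Abca1 was 238-fold higher (200.4 to 288). Further genes with firm bounds were the carbonic anhydrase gene Car4, at least 524-fold higher over 0 counts, the elastase gene Mmp12, at least 324-fold, Igfbp6 (436-fold, 205 to 1478) and Fam71f2, with 1364 counts against 2 (ratio 645, 223 to 6657).

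Granule genes were far lower in control MDSCs than in bone marrow. Secondary and tertiary granule genes had a median of -2.98, with 17 of 18 lower, including Camp (84.7-fold, 79.8 to 90.1), Ltf (31.0-fold) and lysozyme, Lyz2 (24.2-fold). Primary granule genes had a median of -3.51, with 8 of 10 lower, including Elane (113-fold, 53.2 to 385) and myeloperoxidase, Mpo (65.5-fold). Neutrophil identity genes had a median of -0.63, with 8 lower, such as Ly6g (13.4-fold), and 5 higher, such as the lectin gene Clec4d (7.07-fold). NADPH oxidase subunit genes had a median of -0.71 (percentile 2.24), with Cybb 19.9-fold (19.1 to 20.7) and Ncf1 2.31-fold lower. S100a8 (1.74-fold), S100a9 (1.71-fold), Itgam (1.40-fold) and Csf3r (1.06-fold) were lower without passing the bound, although S100a8 (2.06-fold) and S100a9 (2.02-fold) passed it with total counts.

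Cell cycle genes were lower as well. Of 35 G2/M genes, 33 were lower and none higher, with a median of -4.58 (percentile 0.0), including the cytokinesis gene Anln (127-fold, 55.6 to 527) and the centromere gene Cenpf (81.9-fold). Aurka was 2.80-fold lower (2.38 to 3.32), at 9.68 against 27.1 CPM, and Aurkb 58.6-fold (28.9 to 174). G1/S genes had a median of -1.63, with 17 lower and 5 higher, including E2f2 (15.1-fold lower). Haematopoietic progenitor genes (-1.47, inside the random lists) included Myb (55.1-fold lower), and the granulocyte transcription factor gene Cebpe was 45.9-fold lower.

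Markers of several other cell types were more abundant in the bone marrow library. Eosinophil, mast cell and basophil markers had a median of -5.43, or -5.37 with genes at 0 counts set to their bound, with 13 of 16 lower. Eosinophil peroxidase, Epx, was at least 129-fold lower, and the basophil protease gene Prss34 167-fold (82.8 to 493). Ear6 had 1 count against 639 (ratio 361, 96.8 to 21404), but Ear genes are near-identical. B and plasma cell markers had a median of -5.09, or -4.83 at the bound, with all 19 lower (Ighm 39.2-fold, Pax5 48.6-fold). Erythroid markers had a median of -3.48, with 11 of 14 lower. T and NK markers had a median of 0.75 inside the random lists. Other genes with the firmest lower bounds were the ubiquitin ligase gene Nedd4 (116-fold, 80.0 to 183), the adhesion gene Ncam1 (108-fold), Nat8l (102-fold), and Fam71b, Lct and Sntb1, with 2, 1 and 1 counts in control (ratios 278, 95.9 to 2875; 350, 93.7 to 20735; and 259, 69.3 to 15351).

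In this comparison 29 of 43 lists lay outside random lists, 20 above and 9 below, and the higher share of called genes was 44.4%. The medians of macrophage (0.31), endothelial (0.65), dendritic (-0.74), epithelial (0.36) and fibroblast markers (0.52) changed sign with the mean (-0.31 and -0.85) or the 10 CPM filter (1.12, -1.02 and -0.63), and that of chemokine receptors (0.17) with total counts (-0.07). The epithelial value rests on 11 of 27 listed genes and leaves out Krt8, Krt19 and Cldn4, which were found in the FPKM table alone, with signal in both tumour libraries and none or almost none in bone marrow. Nuclear oxidative phosphorylation genes (-0.52) and mitochondrially encoded genes (0.52) lay inside the random lists. Lists that moved inside under another setting were myeloid transcription factors (69.5) and MHC class II genes (95.7) with means, lipid (94.98) and ribosomal protein genes (96.6) with the 10 CPM filter, and neutrophil identity (13.3) and NADPH oxidase genes (20.1) without matching. Checkpoint (99.94) and heat shock genes (99.97) with means, cholesterol genes (98.87) with the 10 CPM filter, and progenitor genes (2.07) and T and NK markers (97.77) without matching moved outside.

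The comparison of alisertib MDSCs with bone marrow neutrophils placed the treated cells against the same reference. Granule genes lay farther from bone marrow than in control MDSCs: secondary and tertiary granule genes had a median of -4.55, with 17 of 18 lower, Camp was 395-fold lower (349 to 450.4), Ltf 141-fold (136 to 147) and Ngp 115-fold (111 to 119). S100a8 (4.56-fold, 4.52 to 4.59) and S100a9 (4.13-fold, 4.10 to 4.15) were called lower here. Primary granule genes had a median of -3.93 and neutrophil identity genes -1.41, with 10 lower and 4 higher, and NADPH oxidase genes had -1.06, with Ncf1 4.47-fold and Cybb 28.3-fold lower. Saa3 was 1812-fold higher (796 to 7485), Arg1 194-fold (110 to 425), Cd274 129-fold (114 to 148), and Nos2 had 2094 counts against 3, a ratio of 665 (265 to 3765).

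Suppressive function genes had a median of 2.05 with 13 of 20 higher, chemokines 4.61, or 4.12 with genes at 0 counts set to their bound, with 16 of 18 higher, cytokines 2.42, NF-kappaB genes 1.63, interferon-stimulated genes 1.89 with 24 of 36 higher, and hypoxia and glycolysis genes 1.87 with 20 of 34 higher. Among single genes, Cxcl3 was 566-fold higher (467 to 700.3), Hilpda 274-fold, Il1a 266-fold, Abca1 235-fold, Spp1 87.2-fold, Car4 at least 346-fold and Mmp12 at least 270.1-fold. Fam71f2 had 1818 counts against 2 (ratio 808, 279 to 8348) and Oas1a 813 against 1 (ratio 603, 162 to 35730). MHC class II genes had a median of 2.05, with H2-Eb1 9.40-fold higher. T and NK markers were higher (median 2.32, 15 of 21 called higher), with Trbc2 at 112 counts against 2 (ratio 50, 16.8 to 520.2), whereas B and plasma cell markers were lower (-2.45, 15 of 19 called lower).

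G2/M genes had a median of -3.58, with 32 of 35 lower, Aurka was 2.64-fold lower (2.26 to 3.10) and Aurkb 62.2-fold (30.7 to 184), and G1/S genes had -0.87. Eosinophil, mast cell and basophil markers had a median of -6.04. Prss34 was at least 384-fold lower and Mcpt8 had 2 counts against 947 (ratio 341, 118 to 3523). Ncam1 was 222-fold lower, the ficolin gene Fcnb 139-fold, the dopamine receptor gene Drd2 at least 127-fold, Fam71b had 2 counts against 821 (ratio 296, 102 to 3055) and Ear6 1 against 639 (ratio 384, 103 to 22746). In all, 33 of 43 lists lay outside random lists, 23 above and 10 below. NADPH oxidase genes (2.44) stood at 7.21 without matching. Their 2.65 under each other scaling came only from a new draw of random lists, as scaling moves all genes alike. Lipid genes (97.68) and G1/S genes (2.25) moved inside under some settings. So did progenitor genes (20.1 with FPKM plus 1), myeloid transcription factors (68.7) with means, T and NK markers (95.8) and heat shock genes (96.5) with the 10 CPM filter, and pro-apoptotic (96.5) and MHC class I genes (at the bound itself) without matching, while checkpoint genes (99.8) moved outside with means.

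**Figure D2:**
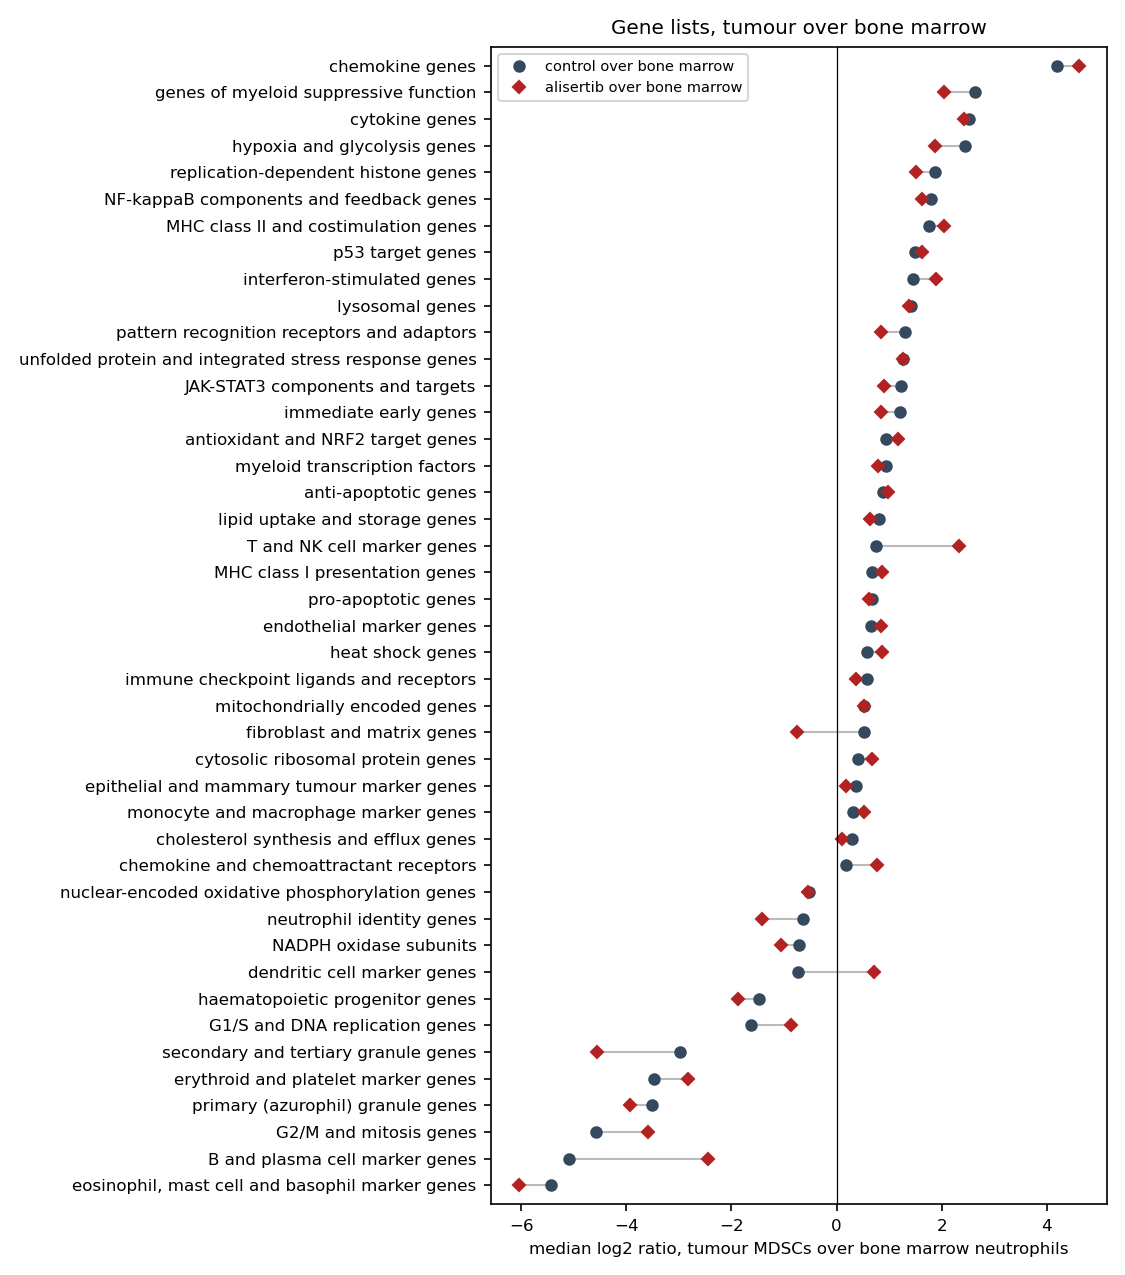
Median log2 ratio over bone marrow neutrophils (horizontal axis) for 43 gene lists (vertical axis), as circles for control and diamonds for alisertib MDSCs. Chemokine genes lay highest in both (4.2 and 4.61), secondary and tertiary granule genes lay lower with alisertib (-4.55) than in control (-2.98), and chemokine receptors and a few marker lists changed sign with the setting.

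**Figure D3:**
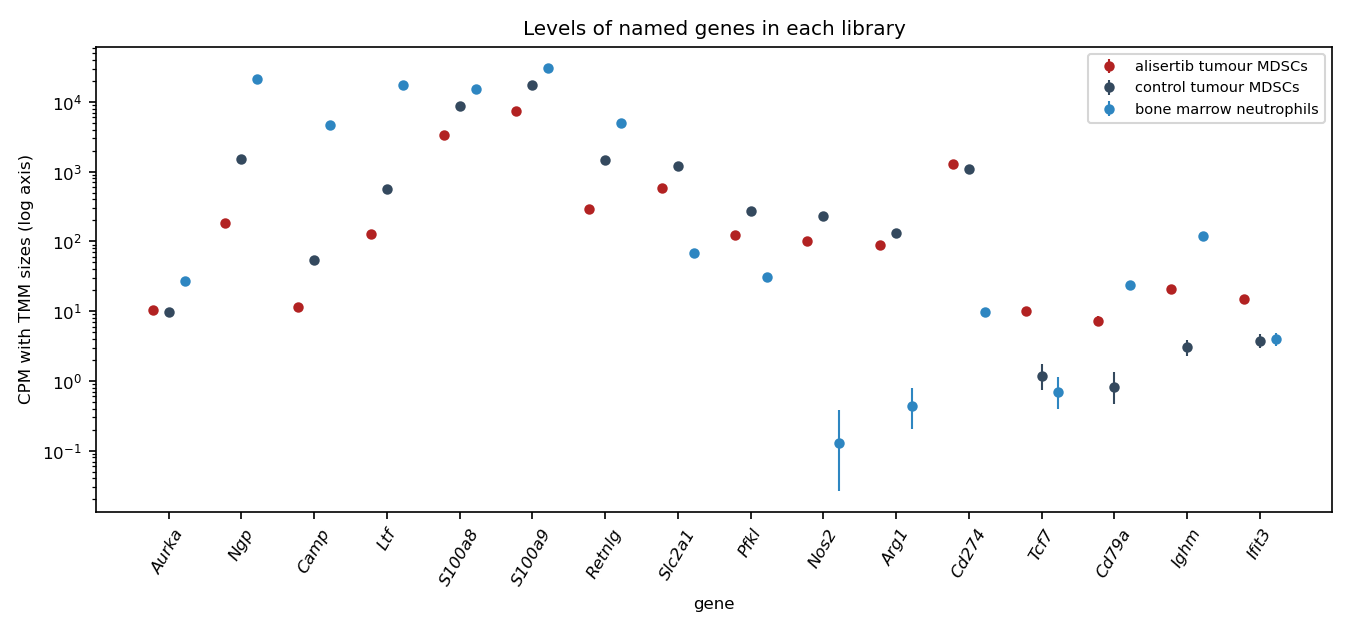
Expression of 16 genes (horizontal axis) in the alisertib, control and bone marrow libraries, as CPM with TMM sizes on a log axis, with 95% Poisson intervals of the counts as bars. Ngp stood at 186 CPM with alisertib and 1509 CPM in control, Tcf7 at 10.1 and 1.18 CPM, and Aurka at 10.3 and 9.68 CPM.

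The differences of alisertib and of bone marrow from control were then set beside each other across the 13019 genes. Their log2 ratios over control had a Spearman correlation of 0.165, a Pearson correlation of 0.183 and a covariance of 0.2923. These are correlations across genes, which are not independent replicates, and both ratios share the control library. A simulation that redrew the counts of all 3 libraries, with alisertib unchanged from control, gave 0.05, 0.081 and a covariance of 0.0605. Dividing the observed control reads between the ratios gave a Spearman correlation of 0.122 and a covariance of 0.1831. The covariance exceeded the simulated value by 0.2319. Of the genes higher with alisertib, 85 were also higher in bone marrow and 15 lower, against 53.7 and 42.9 for independent lists. Of the genes lower with alisertib, 59 were higher in bone marrow and 53 lower, against 35.3 and 28.2. With the control reads divided between the ratios, which leaves fewer genes called, they were 50, 11, 55 and 48, against 37.6, 31.6, 30.2 and 25.4 for independent lists of that size. Dividing reads of 1 pool removes shared counting error only, and none of these reference values includes variation between pools, so the relation may reflect the control pool itself.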

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

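The choice to look at genes present only in the table of FPKM values, and the rule for picking among them, were made after the tables were seen. The rule took protein-coding genes absent from the count table with an FPKM of at least 3 in a tumour library and more than 30 times the value in bone marrow neutrophils, which met 5 genes. They stood out as signal in values that the comparisons did not use. The rule itself asks for little signal in bone marrow, and of the genes absent from the count table whose rebuilt counts were whole, 91.7% had at most 3 counts there, against 23.1% of count table genes, so near absence from bone marrow does not set these 5 apart.

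The keratin gene Krt8 had an FPKM of 6.64 with alisertib, 5.17 in control and 0.0238 in bone marrow. Il1f6, encoding interleukin-36 alpha, had 5.25 with alisertib, 4.12 in control and 0.146 in bone marrow. The chemokine gene Cxcl14 had 4.95 in control, 3.49 with alisertib and 0 in bone marrow. The phosphatase gene Dusp14 had 4.79 in control, 1.95 with alisertib and 0 in bone marrow. The enolase gene Eno2 had 4.24 in control, 3.51 with alisertib and 0.00911 in bone marrow. No biological or technical explanation was tested for these 5 genes.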

How the results depend on the processing

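The alternatives that added genes of the FPKM table and left out the lymphocyte lists were chosen after the result was seen, and the others before. No paired analysis was possible because each group holds one library, and leave-one-out cannot be done. Genes higher and lower with alisertib over control (234 and 154) numbered 422 and 83 with total counts, 392 and 90 without the 20 most abundant genes, 617 and 640 at a 1.5-fold bound, 48 and 10 at a 4-fold bound, 1006 and 631 at a log2 ratio of at least 1, and 607 and 452 with FPKM plus 0.1. The higher genes alone moved to 66 with the 10 CPM filter and to 85 with FPKM plus 1. Control over bone marrow (2386 and 2985) gave 1564 and 1956 with the 10 CPM filter and 1104 and 1297 at a 4-fold bound. Alisertib over bone marrow (2436 and 2908) gave 1482 higher with the 10 CPM filter and 1134 and 1250 at a 4-fold bound. Bounds and filters set the number of genes called or tested by construction, and for the others the cause was not tested. The remaining counts stayed within 1.5 times, such as 207 and 185 for alisertib over control with DESeq2, 238 and 157 with the added genes and 211 and 154 without the lymphocyte lists. The correlation across genes of 0.165 became 0.225 with no filter, 0.129 with the 10 CPM filter, 0.141 with FPKM and 0.122 with divided control reads. Spearman correlations between libraries, in the order no filter, 10 CPM filter, were 0.97 and 0.974 for alisertib and control, 0.882 and 0.671 for control and bone marrow (0.785 with FPKM), and 0.881 and 0.647 for alisertib and bone marrow (0.772 with FPKM). Lists outside random lists numbered 15 to 18, 27 to 29 and 26 to 32 under the alternatives. Of list percentiles, 308, 327 and 317 kept their side of the bounds in the 3 comparisons in the order given, 12, 6 and 20 moved inside and 18, 5 and 1 outside. These counts include the scalings, which move all genes of a comparison alike. Percentiles under them could change only through a new draw of random lists. No list outside random lists changed the sign of its median. With total counts, 11 of 64 named genes called between alisertib and control were no longer called. Depth set a floor of 0.130 to 0.154 CPM.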

Other observations

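The tests of a lower share of the main cell type, of dilution, of scaling, of abundance and of GC content were chosen after the result was seen, and so were setting G2/M genes and the correlations against the question of bone-marrow-like neutrophils and leaving out Cd27 and Cxcr5 from further lymphocyte genes because other lists hold them. The T cell receptor complex gene Cd3d stood apart from other T cell genes: it had 3143 counts in bone marrow, 170 in control (15.6-fold lower than bone marrow) and 129 with alisertib (21.8-fold lower), while Cd3e had 2, 17 and 98 counts and Trbc2 2, 23 and 112 in the same libraries. The mitochondrial ribosomal RNA gene mt-Rnr1 was 9.93-fold higher in control than in bone marrow and 4.96-fold higher with alisertib, and mt-Rnr2 4.32-fold and 3.39-fold, whereas the messenger mt-Cytb was 1.20-fold and 1.44-fold higher, the former with a log2 ratio of 0.26 that became -0.01 with total counts without the 20 most abundant genes.

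Lymphocyte genes were higher with alisertib across both lineages. A lower share of the main cell type that raises the markers of every other type alike was argued against. The lymphocyte lists lay 2.2 log2 units (1.30 to 2.82, by resampling genes) above the macrophage, eosinophil, epithelial, fibroblast and endothelial lists. Few of those were measurable: 4 of 16 eosinophil, mast cell and basophil markers reached 1 CPM in control and 7 of 25 fibroblast genes passed the filter. A lower share that raised other types unequally stays open, and macrophage markers themselves lay above random lists (97.88). A candidate explanation is more T and B cells in the alisertib sort, since 16 further T cell genes had a median log2 ratio of 1.3 and 11 further B cell genes 1.81, with the lower percentile of the pair at 100. Among the named markers Tcf7 stood at 10.1 CPM and Ighm at 21.1 CPM with alisertib, and 15 of 21 T and NK markers and 3 of 19 B markers, none held by another list, reached 1 CPM in the control library, in sorts of purity above 90% whose gates are not given. With 1 library per group, alisertib treatment and a difference between the pools cannot be told apart.

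Secondary granule genes were lower with alisertib by more than other neutrophil genes. Dilution of neutrophils by other cells was argued against by a difference of -0.91 log2 units from the other neutrophil identity genes, although the interval (-1.26 to -0.04) came close to 0. With total counts the granule median was -1.23. That scaling adds 0.27 to every gene of the comparison, so the value follows from the main median. It shows only that the median stays well below 0 under that scaling. Whether the alisertib pool held fewer bone-marrow-like neutrophils stays open, because values point both ways. Genes at least 16-fold higher in bone marrow than in control, with at least 200 counts there and outside the fixed lists, had a median at percentile 0.09 of random lists, but 16 of 23 were below 0 and their median of -0.31 was far smaller than the -1.5 of the granule genes. G2/M genes, of which 33 of 35 were lower in control than in bone marrow, had a median of 0.52 with alisertib. The random lists reached 0.51, and none of the 35 was called. The list moved inside them with means, FPKM plus 1 and the 10 CPM filter. Of genes higher with alisertib, 85 were higher in bone marrow against 53.7 for independent lists, and 15 were lower against 42.9. Of genes lower with alisertib, 59 were higher in bone marrow against 35.3, but 53 were lower against 28.2. Both directions exceeded independent lists there, so the 59 do not point to bone-marrow-like cells. The 85 include the 11 B and plasma cell markers called higher, so they do not single out neutrophils. The differences of alisertib and bone marrow from control correlated positively across genes (0.165, or 0.122 with divided control reads), lymphocyte genes included. Alisertib treatment stays open, as no second pool was measured.

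Hypoxia and glycolysis genes were lower with alisertib. The size of this difference depends on the scaling, since total counts add 0.27 to every log2 ratio of the comparison, against a list median of -0.61. Ero1l, Pfkl, Egln3 and Slc2a1 were then no longer called. As the whole cause, trends of the ratio with abundance and with GC content were argued against by genes outside the list: over 20 bins their lowest median log2 ratio was -0.32 (-0.35 to -0.29) by abundance and -0.06 (-0.10 to -0.01) by GC content, above the list's -0.61 (-0.75 to -0.41). Abundance may account for part of it. Dilution of neutrophils by other cells was not set aside, as the list differed by -0.03 log2 units (-0.27 to 0.34) from the other neutrophil identity genes. Similar medians are no evidence that dilution took place, and the labels give a purity above 90% for the sorts. Alisertib treatment stays open and was not tested.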
